A study of Mus musculus with 8 samples.

How the data were processed

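The series holds 8 Affymetrix arrays of mouse liver total RNA, 4 labelled WT and 4 labelled HNF6KO, all male, aged 12 weeks and taken at ZT10 (5 pm). RNA was extracted with Trizol, labelled with biotin and hybridised by a whole-transcript labelling kit, per the labels' protocols. The authors deposited 1 table with 1 value per probe set and array. The deposited values are read here as log2 expression, since they run from 3.69 to 14.1 with array medians of 6.89 to 6.97. The base of the logarithm and the method of background correction, normalization and summarisation are not given in the sources used here, so any change the authors' normalization made to the scale of an array cannot be undone. Upper quartiles lay between 8.34 and 8.51. If the authors brought the arrays to a common scale, a true shift of most transcripts would not be visible in these values. No value was missing, and no value was changed, rescaled or filtered before the tests.

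The table holds 22725 probe sets. The platform annotation paired 21113 of them with 1 gene symbol, 43 with several and 1569 with none here, and the last 2 kinds stayed out of the gene comparison. An Entrez identifier of 21044 probe sets was found in the reference gene table (assembly GRCm38.p6, used only for names), which updated 0 symbols. Where a gene had more than 1 probe set (883 genes), the one with the highest mean over the 8 arrays stood for it, which left 19540 genes. The genome build of the annotation is not given in the sources used here, so no coordinates are printed. Probe sets of large gene families (cytochromes P450, major urinary proteins, sulfotransferases, glutathione transferases and others) can bind transcripts of relatives, and the signal of a dim gene lies near the background of the array, where a fold change is understated.

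HNF6KO was compared with WT in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, no trend, no weights), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Adjusted p-values of genes are from this test, log2 changes are HNF6KO minus WT, and their SE is the moderated one. Before the data were examined, 42 gene lists were written from general knowledge of liver, 31 of processes and 11 of cell type markers, with 927 genes of which 799 were measured, 4 of them through an older symbol. Lists were tested with camera (preset correlation 0.01, two-sided) against all other genes, and adjusted over the 42 lists. Camera with a correlation estimated per list, and fry, were the alternatives. Members were counted as risen or fallen over all genes, and also with the adjustment made within the list. List means per array were compared by an exact permutation test over the 70 assignments of 8 arrays to 4 and 4, whose smallest two-sided p is 0.0286. Overlaps of lists with changed genes were tested with Fisher's exact test against all 19540 genes, and adjusted over 4 such tests.

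The rule for named genes was set at the same time. It takes Onecut1, Onecut2, Onecut3, Nr1d1, Nr1d2, Hdac3 and Ncor1, the 12 largest risers and the 12 largest fallers among genes past the threshold whose groups do not overlap, and up to 4 members per list with the smallest p. Gene models without a proper name were not named and stayed in the counts. Under this rule 57 genes are reported, among them 30 past the threshold. Further genes are named where it is said that they were chosen after their values were seen, and Xist as a check of sex.

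Alternatives set beforehand were quantile normalization, median centring and cyclic loess of the deposited values, a filter at the 40th percentile of mean expression, an intensity trend with robust variances, array quality weights, a plain two-sample test, thresholds of 0.01, 0.1 and 1.5-fold, the mean of a gene's probe sets, every probe set on its own, the array number as a replicate block, and each array left out in turn. The labels give no hybridisation batch or date. Because the arrays separated by number, fits with the split of arrays 1 and 2 from arrays 3 and 4 as a term, within each side of it, and without HNF6KO arrays 3 and 4 were added after the data were seen. No pair of arrays was a copy of another (Pearson r across probe sets 0.987 to 0.997).

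The limma step was tested on simulated data for this comparison, with 200 of 19540 genes changed, normal noise, and each gene's own mean and residual spread. It called 76.0% of 50 genes changed by 0.5 on the log2 scale and 94.0% of 50 changed by 1. It called 98.0% of 50 changed by 2, 100.0% of 50 changed by 4, and 12 of 19340 unchanged genes. These rates hold for that simulated noise. The effect on them of differences that many genes share, such as the separation of the arrays by number, was not tested.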

Results

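Gene expression in mouse liver was measured on 8 Affymetrix arrays, 4 from wild-type (WT) livers and 4 from livers depleted of HNF6 (HNF6KO). HNF6 is a liver-enriched homeodomain transcription factor encoded by the gene Onecut1 (Entrez 15379). The labels describe every sample as liver of a male C57B/6 mouse aged 12 weeks, kept on chow under a light and dark cycle and sampled at ZT10, given as 5 pm. ZT10 is the point 10 h after lights on, when the clock repressor REV-ERBα is near its daily peak in mouse liver. The comparison asks which liver transcripts differ when HNF6 is lost at that time of day, with lipid metabolism and REV-ERBα named in the study's title. The deposited values covered 19540 genes, each represented here by 1 probe set, on a scale from 3.69 to 14.1 that reads as log2, and the array medians lay between 6.89 and 6.97. The 4 arrays per group limit the precision of each value. The labels do not say whether the arrays came from separate animals. The p-values measure only the spread between these samples.

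The Onecut1 transcript was lower on every HNF6KO array than on any WT array. Its log2 values were 10.17, 9.87, 10.45 and 10.52 on WT arrays 1 to 4 and 9.32, 9.05, 8.67 and 8.70 on HNF6KO arrays 1 to 4. The group means were 10.25 ± 0.30 (SD, n = 4) in WT and 8.93 ± 0.31 (SD, n = 4) in HNF6KO. Onecut1 fell by 1.32 ± 0.18 (SE) on the log2 scale, or 2.49-fold (limma, adjusted p = 0.0273). Which part of the transcript the probe set targets, and which part the knockout removes are not given in the sources used here. The remaining signal does not measure residual HNF6 activity. The call was lost when any 1 of WT arrays 1, 3 and 4 or HNF6KO arrays 3 and 4 was left out, with log2 changes of -1.34 to -1.23 and adjusted p = 0.0633 to 0.0954.

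The paralogs Onecut2 and Onecut3, and the genes of the REV-ERB corepressor pathway, did not pass the test. The log2 change was -0.11 ± 0.09 for Onecut2 (adjusted p = 0.775) and -0.03 ± 0.09 for Onecut3 (adjusted p = 0.963). Nr1d1, which encodes REV-ERBα, had a log2 change of -0.76 ± 0.31 (SE, n = 4 per group, adjusted p = 0.477), and its WT arrays spread over an SD of 0.67. Nr1d2, encoding REV-ERBβ, had a log2 change of -0.02 ± 0.06 (adjusted p = 0.974), and Hdac3, the histone deacetylase recruited by REV-ERB, one of -0.07 ± 0.07 (adjusted p = 0.838). Ncor1 was not analysed here.

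**Figure D1:**
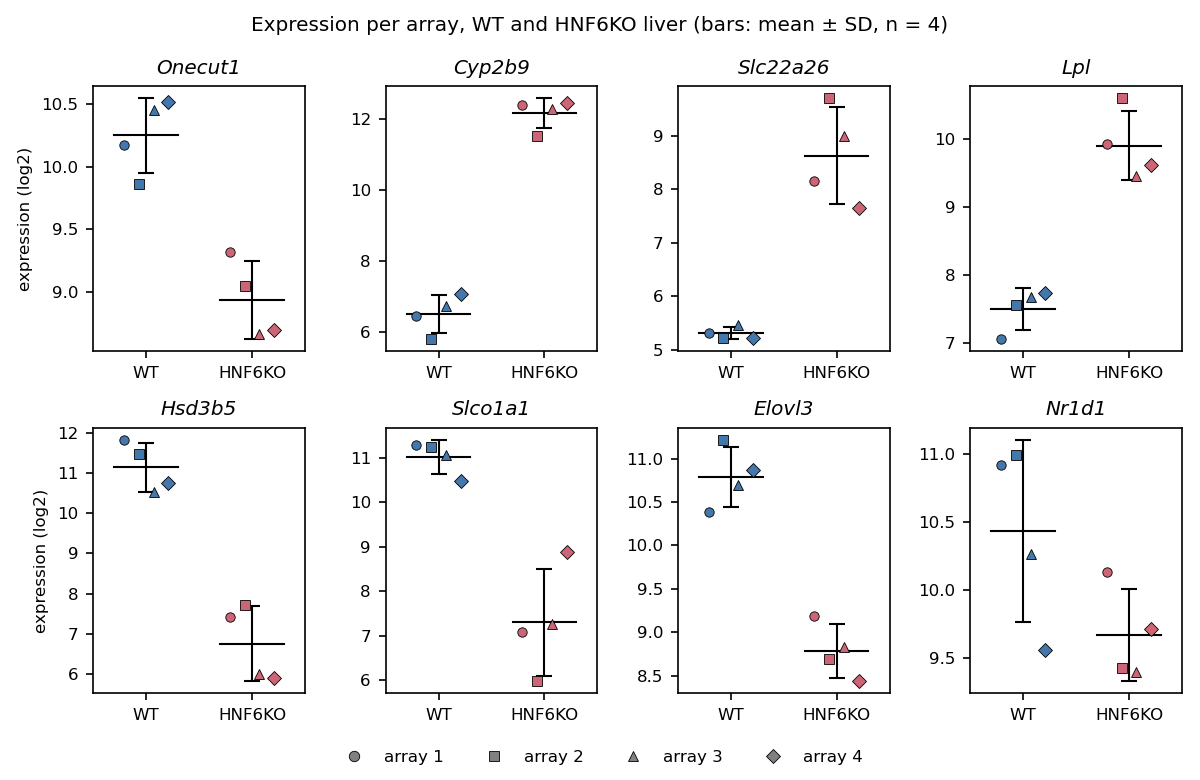
Expression of 8 genes on each array, with log2 expression on the vertical axis (each panel has its own range, not starting at 0) and the 2 groups on the horizontal axis; symbols give the array number, and bars the mean ± SD (n = 4). The arrays of the groups do not overlap for the first 7 genes, while the WT values of Nr1d1 reach into the HNF6KO range (adjusted p = 0.477).

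Loss of HNF6 went with large and opposite changes of a few liver enzymes and transporters. Cyp2b9, a cytochrome P450 of female-type liver, rose from 6.51 ± 0.54 in WT to 12.16 ± 0.43 in HNF6KO (SD, n = 4), a log2 change of 5.65 ± 0.28 (SE) or 50.2-fold (adjusted p = 1.35e-04). In WT that level stood at the 40.5th percentile of genes, and in HNF6KO at the 99.0th. Hsd3b5, a steroid dehydrogenase of male-type liver, fell from 11.14 ± 0.61 to 6.76 ± 0.94, a log2 change of -4.39 ± 0.46 or 20.9-fold (adjusted p = 0.00785). The organic anion transporter Slco1a1 fell by 3.72 ± 0.52 on the log2 scale, or 13.2-fold (adjusted p = 0.0279). Among the other large risers were the organic anion transporter Slc22a26 (log2 change 3.32 ± 0.37, adjusted p = 0.0111) and Lpl, encoding the lipoprotein lipase that releases fatty acids from circulating triglyceride (2.41 ± 0.25, adjusted p = 0.00773).

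In all, 78 of 19540 genes passed an adjusted p of 0.05, 31 higher and 47 lower in HNF6KO, and 21 of them differed by 2-fold or more (9 higher and 12 lower). Each of the 78 had its 4 HNF6KO arrays on one side of all 4 WT arrays. Over all genes this separation was seen for 1107, or 5.67%, where chance gives 2.86%. At an unadjusted p of 0.05, 1859 genes passed. The next risers by size were the flavin monooxygenase Fmo4 (1.54 ± 0.15), the transporter Slc22a27 (1.48 ± 0.15), the trypsin inhibitor Spink1 (1.20 ± 0.18) and Ildr2 (1.11 ± 0.17). Spink1 lay below the median gene (6.97) in both groups, at 5.15 in WT and 6.36 in HNF6KO. Smaller rises were seen for Chic1 (0.78 ± 0.07), the glutathione transferase Gstm2 (0.78 ± 0.12), Akr1d1, the bile acid and steroid 5β-reductase (0.66 ± 0.10), the proline dehydrogenase Prodh (0.57 ± 0.08) and Mpv17l (0.57 ± 0.08), as log2 change ± SE, with adjusted p from 0.00402 to 0.0412. Besides Hsd3b5, Slco1a1 and Onecut1, the largest falls were in the P450 Cyp2c54 (-2.89 ± 0.29), the fatty acid elongase Elovl3 (-2.01 ± 0.19), the vasopressin receptor Avpr1a (-1.53 ± 0.22), the complement component C6 (-1.25 ± 0.14), and the manganese exporter Slc30a10 (-1.18 ± 0.10). After these came the sorting receptor Sort1 (-1.12 ± 0.16), Dock8 (-1.09 ± 0.15), the carbonic anhydrase Car1 (-1.08 ± 0.14) and the major urinary protein Mup3 (-1.05 ± 0.08), and the adjusted p of these falls ran from 0.00228 to 0.0322. Cyp2b9, Slc22a26, Slc22a27, Hsd3b5, Slco1a1, Cyp2c54, Gstm2, Gstp1 and Mup3 belong to families of near-identical or closely related genes. Their probe sets can pick up relatives, so the member that changed is uncertain. The count of 78 was 26, 16, 28 and 40 without WT arrays 1 to 4 in turn and 27 and 30 without HNF6KO arrays 3 and 4. Of the named genes, 10 stayed past the threshold whichever array was left out (Cyp2b9, Lpl, Fmo4, Slc22a27, Chic1, Hsd3b5, Cyp2c54, Elovl3, Slc30a10 and Mup3). Another normalization, variance model, filter, probe set choice or block ended the calls of Spink1, Slco1a1, Gstm2, Mpv17l, Mbl1, Sult1b1, Gstp1, C2, Pcna and Mthfd1 in at least 1 case each.

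The list of genes known to be more active in female than in male liver shifted upward in these males, and the list of male-biased genes shifted downward. Of 28 measured female-biased genes, 3 rose (Cyp2b9, Slc22a26 and Slc22a27), 0 fell and 25 did not pass over all genes. When adjusted over the list alone, 11 rose and 1 fell. The median log2 change was 0.55, with 20 of 28 members above 0, and Cyp2c38, a P450, had a log2 change of 1.77 ± 0.32 (adjusted p = 0.0670). The 11 members outside families of near-identical genes, a grouping made after the result was seen, had a median of only 0.07, with 6 above 0, 5 below 0 and 0 risen. Of 31 measured male-biased genes, 6 fell (Hsd3b5, Slco1a1, Elovl3, C6, Mup3 and the glutathione transferase Gstp1), 0 rose and 25 did not pass. When adjusted over the list alone, 11 fell and 1 rose. Their median log2 change was -0.24, with 26 of 31 members below 0, and Gstp1 fell by 0.56 ± 0.09 on the log2 scale (adjusted p = 0.0454). The 15 members outside such families had a median of -0.18, with 12 below 0 and 2 fallen. The shift of each list against all other genes passed camera (adjusted p = 1.34e-11 for the female-biased and 2.00e-09 for the male-biased list), and each had adjusted p = 0.0208 with an estimated correlation. The 3 risers compare with 0.0444 members expected among 31 higher genes (Fisher's exact test, two-sided, adjusted p = 2.31e-05), and the 6 fallers with 0.0746 expected among 47 lower genes (adjusted p = 3.91e-10). Fisher's test counts genes as independent, while all 3 risers belong to such families, and Slc22a26 and Slc22a27 may share signal. Its p does not measure the spread between arrays. The mean of each list lay apart between the groups on every array, which gave the smallest p that 4 against 4 arrays allow (exact permutation test, two-sided, p = 0.0286). Of the 42 lists 11 reached this p, and 0 passed this test after adjustment (exact adjusted p = 0.109 for both sex-biased lists). The medians were 0.42 and 0.32 for the female-biased list within the arrays numbered 1 and 2 and within those numbered 3 and 4, and -0.22 and -0.25 for the male-biased list.

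**Figure D2:**
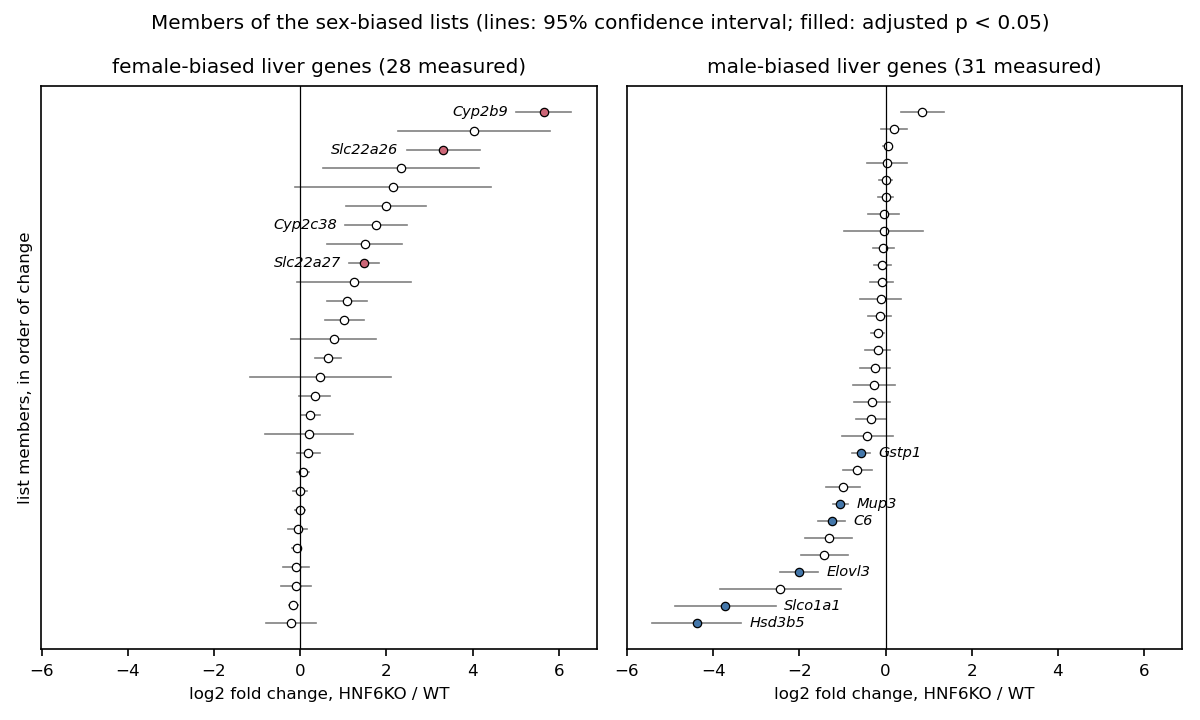
Log2 fold change, HNF6KO over WT, on the horizontal axis for each measured member of the female-biased list (28 genes, left) and the male-biased list (31 genes, right), ordered by change; lines are 95% confidence intervals and filled points passed an adjusted p of 0.05. The 3 filled points on the left lie above 0 (5.65 for Cyp2b9) and the 6 on the right below 0 (-4.39 for Hsd3b5).

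Lists of de novo lipogenesis and of fatty acid uptake leaned upward, while cholesterol synthesis leaned downward. Lpl rose. Of 12 measured genes for fatty acid uptake and binding, 1 rose (Lpl) and 11 did not pass, and 3 rose when adjusted over the list alone. The fatty acid translocase Cd36 had a log2 change of 0.99 ± 0.30 and the transporter Slc27a5 one of 0.32 ± 0.07 (adjusted p = 0.131), and neither passed over all genes. That list passed camera (median 0.14, adjusted p = 0.00117) but had adjusted p = 0.117 with an estimated correlation. Of 18 measured genes of de novo lipogenesis, which builds fatty acids from acetyl-CoA, 0 passed over all genes in limma, 7 lay higher at an unadjusted p of 0.05, and 6 rose when adjusted over the list alone. Among these, the acetyl-CoA carboxylase Acacb had a log2 change of 0.74 ± 0.14 (adjusted p = 0.0806 over all genes) and the desaturase Scd1 one of 1.08 ± 0.29 (adjusted p = 0.239). With the split of arrays 1 and 2 from arrays 3 and 4 as a term, which was chosen after the data were seen, 2 members passed. These were Acacb (adjusted p = 0.0398) and the lipogenic regulator Thrsp (0.88 ± 0.27, adjusted p = 0.0246 with the term and 0.307 without), which was chosen after its values were seen. The lipogenesis list passed camera (median 0.35, adjusted p = 1.66e-06) but had adjusted p = 0.240 with an estimated correlation, and its median was 0.16 within arrays 1 and 2 and 0.43 within arrays 3 and 4.

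Cholesterol synthesis passed camera downward (20 measured, 0 passing, median -0.17, adjusted p = 0.0254), with adjusted p = 0.731 with an estimated correlation. Its median was -0.30 within arrays 1 and 2 and -0.03 within arrays 3 and 4. Tm7sf2, a sterol reductase and the 1 member that fell when adjusted over the list alone, had a log2 change of -0.40 ± 0.10 (adjusted p = 0.169). Lipoprotein assembly and secretion passed camera upward (19 measured, 0 passing, median 0.03, adjusted p = 0.0420), with adjusted p = 0.240 with an estimated correlation. Apoa4, the 1 member there that rose when adjusted over the list alone, had a log2 change of 0.86 ± 0.19 (adjusted p = 0.134 over all genes). Triglyceride synthesis and lipid droplets did not pass (24 measured, 0 passing, median -0.05, adjusted p = 0.432), and its member Fitm1 had a log2 change of -0.85 ± 0.33 (adjusted p = 0.456). Fatty acid oxidation and ketogenesis did not pass either (28 measured, 0 passing and 6 lower at an unadjusted p of 0.05, median -0.06, adjusted p = 0.0906), and 1 member fell when adjusted over the list alone. This list passed downward after quantile normalization (adjusted p = 0.0349) or cyclic loess (0.0252), without WT array 4 (0.00269), without HNF6KO array 3 (0.0460), 4 (0.0303) or both (0.0196), and within arrays 1 and 2 (0.00143). Its PPARα target genes Acot1 and Cyp4a14 had log2 changes of -1.05 ± 0.24 (adjusted p = 0.150) and -1.38 ± 0.53 (adjusted p = 0.444).

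Bile acid, detoxification, amino acid and complement genes each held members that passed. Those of the bile acid, phase 2 and complement lists went both ways, the amino acid member rose and the phase 1 member fell. Of 28 measured genes of bile acid synthesis and transport, Akr1d1 rose, Slco1a1 fell and 26 did not pass, and 3 rose and 1 fell when adjusted over the list alone. The list did not pass camera (median -0.05, adjusted p = 0.920), and the related transporter Slco1a4 had a log2 change of 1.65 ± 0.37 (adjusted p = 0.144). Of 27 measured genes of phase 2 detoxification and oxidative stress, Gstm2 and the sulfotransferase Sult1b1 (0.55 ± 0.09, adjusted p = 0.0433) rose, Gstp1 fell and 24 did not pass. When adjusted over the list alone, 4 rose and 1 fell. This list passed camera (median 0.17, adjusted p = 6.89e-05), with adjusted p = 0.417 with an estimated correlation, and its median was 6.17e-04 within arrays 1 and 2 and 0.28 within arrays 3 and 4. Of 25 measured phase 1 genes, Cyp2c54 fell and 24 did not pass (4 rose and 2 fell when adjusted over the list alone). Fmo1 had a log2 change of 0.66 ± 0.16 (adjusted p = 0.182), and the phase 1 list did not pass (median 0.04, adjusted p = 0.281). Of 22 measured genes of the urea cycle and amino acid catabolism, Prodh rose and 21 did not pass. When adjusted over the list alone 5 rose, among them the histidase Hal (0.31 ± 0.05, adjusted p = 0.0536 over all genes). That list passed camera (median 0.11, adjusted p = 4.13e-07), with adjusted p = 0.207 with an estimated correlation. Of 37 measured complement and coagulation genes, C6 and the mannose-binding lectin Mbl1 (-0.92 ± 0.13, adjusted p = 0.0285) fell, C2 rose (0.38 ± 0.06, adjusted p = 0.0404) and 34 did not pass. When adjusted over the list alone 1 rose and 4 fell, and the list as a whole did not pass (median -0.01, adjusted p = 0.680).

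The core circadian clock list did not pass at this time point. Of its 19 measured genes 0 passed over all genes in limma, 5 were lower at an unadjusted p of 0.05, and 2 fell when adjusted over the list alone. Those were Clock, the partner of BMAL1 (-0.40 ± 0.10, adjusted p = 0.184 over all genes), and the repressor Bhlhe41 (-0.84 ± 0.22, adjusted p = 0.222). With the split of arrays 1 and 2 from arrays 3 and 4 as a term, Clock passed (adjusted p = 0.0143) and Bhlhe41 did not (adjusted p = 0.0815). The list's median was 0.01 and its mean -0.10 (camera adjusted p = 0.435). It passed downward in 1 fit, without HNF6KO arrays 3 and 4 (median -0.06, adjusted p = 0.0404). Of 22 measured clock output genes of liver, Elovl3 and Avpr1a fell and 20 did not pass, and 1 rose and 2 fell when adjusted over the list alone. The riser there was Nampt, an enzyme of NAD synthesis (0.75 ± 0.15, adjusted p = 0.0891 over all genes), and the list did not pass (median 0.03, mean -0.04, adjusted p = 0.965). Liver transcription factors did not pass (23 measured, 0 passing and 3 lower at an unadjusted p of 0.05, median -0.08, adjusted p = 0.0873). The pioneer factor Foxa1 had a log2 change of -0.45 ± 0.18 (adjusted p = 0.450). The list of HNF6 and REV-ERB partner factors did not pass either (11 measured, 0 passing and 2 lower at an unadjusted p of 0.05, median -0.07, adjusted p = 0.0906). With the split of arrays 1 and 2 from arrays 3 and 4 as a term, both of these lists passed downward (adjusted p = 0.0123 for liver transcription factors and 0.0285 for partner factors). The first also passed without WT array 1 (adjusted p = 0.0442) or HNF6KO array 3 (0.0102), and the second without WT array 4 (0.0447) or HNF6KO array 3 (0.0453). Both passed within arrays 1 and 2 (0.00586 and 0.0339) and without HNF6KO arrays 3 and 4 (0.00821 and 0.0391). Growth hormone and STAT5 signalling did not pass (15 measured, 0 passing and 2 higher at an unadjusted p of 0.05, median 0.01, adjusted p = 0.213). The log2 change was 0.85 ± 0.22 for the feedback inhibitor Socs2 (adjusted p = 0.208) and 0.13 ± 0.06 for the receptor gene Ghr (adjusted p = 0.511). Another, dimmer Socs2 probe set had a log2 change of 0.33 (limma, adjusted p = 0.408 over all probe sets). Socs2 is also on the male-biased list, which shifted downward.

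The interferon response list shifted upward in HNF6KO, mainly on arrays 3 and 4, while Kupffer markers were higher on those arrays in both groups. Of 29 measured, 27 had a log2 change above 0, 8 were higher at an unadjusted p of 0.05 and 0 passed over all genes in limma or when adjusted over the list alone. Ifih1, a sensor of viral RNA, had a log2 change of 0.57 ± 0.16 (adjusted p = 0.257) and the guanylate-binding protein Gbp3 one of 0.93 ± 0.35 (adjusted p = 0.429). The list passed camera (median 0.38, adjusted p = 8.52e-09), with adjusted p = 0.405 with an estimated correlation. The list mean relative to WT was -0.09, 0.21, 0.48 and 0.75 on HNF6KO arrays 1 to 4, and the list's median change was 0.08 within arrays 1 and 2 (adjusted p = 0.163) and 0.61 within arrays 3 and 4. The mean of the Kupffer list, relative to WT in the same way, was -0.17, -0.57, 0.56 and 0.39 on these arrays, and its median change within arrays 3 and 4 was 0.22 (adjusted p = 1.61e-04). On WT arrays 1 to 4 the Kupffer mean was -0.59, 0.04, 0.21 and 0.34, while the interferon mean was -0.09, 0.04, 0.05 and -0.01. A part of Kupffer cells in the interferon shift was not tested.

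**Figure D3:**
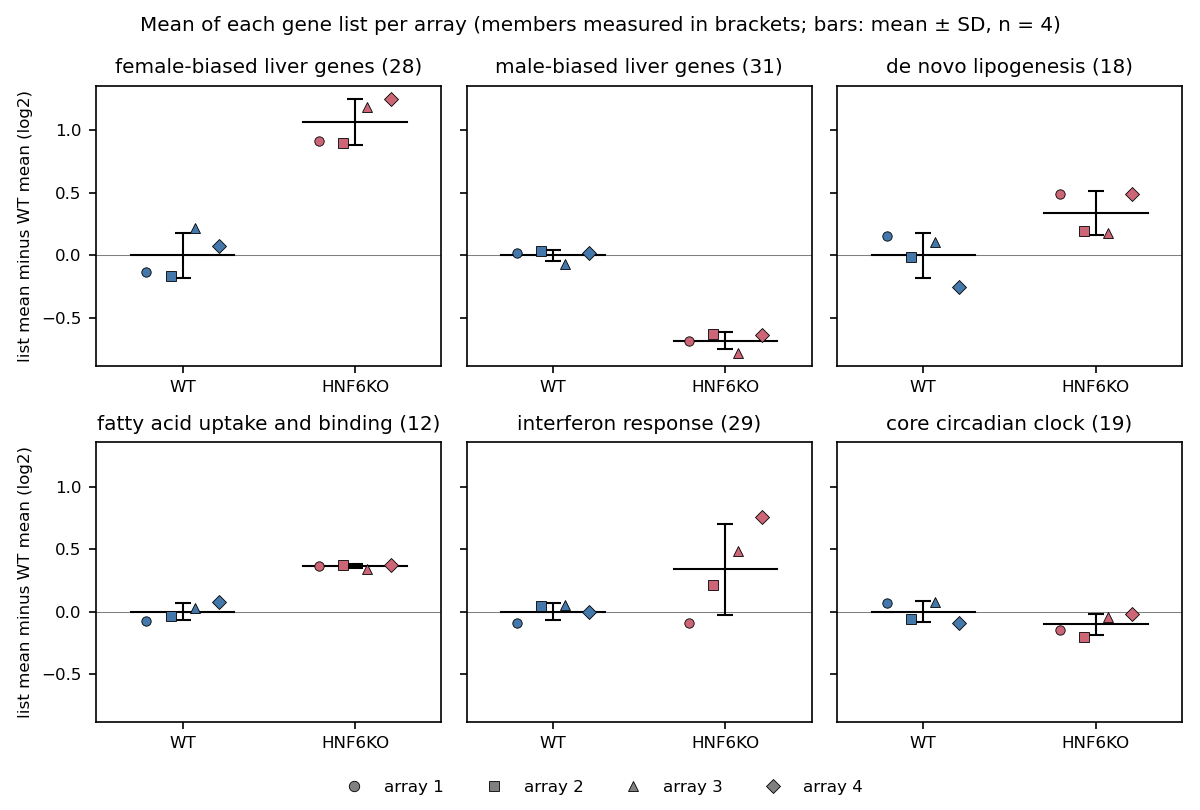
Mean log2 value of 6 gene lists on each array, relative to the WT mean of the same list, with the 2 groups on the horizontal axis; symbols give the array number, bars the mean ± SD (n = 4), and the number in brackets the measured members. The HNF6KO means of the sex-biased lists lie apart from WT, while those of the interferon list run from -0.09 to 0.75.

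The cell cycle list held 1 riser, Pcna, the sliding clamp of DNA replication (0.37 ± 0.06, adjusted p = 0.0433). The other 28 of its 29 measured genes did not pass, 1 rose when adjusted over the list alone, and 26 had a log2 change above 0 (median 0.11, camera adjusted p = 1.24e-07, with adjusted p = 0.240 with an estimated correlation). In the fetal liver list Lpl and Spink1 rose and 22 of 24 did not pass, and the same count of 2 rose when adjusted over the list alone (median 0.03, camera adjusted p = 0.00363, with adjusted p = 0.146 with an estimated correlation). Of 18 measured genes of one-carbon and methionine metabolism, the folate enzyme Mthfd1 rose (0.28 ± 0.05, adjusted p = 0.0433) and 17 did not pass, 1 rose when adjusted over the list alone, and the list did not pass (median 0.08, adjusted p = 0.0772).

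Marker genes of other cell types had small median changes between the groups. The median log2 change lay between -0.07 and 0.11 for the 10 lists of non-hepatocyte markers. Blood was the only such list to pass camera (erythroid cell and blood, 6 of 15 genes measured, median -0.07, mean -0.38, adjusted p = 0.00303, with adjusted p = 0.240 with an estimated correlation). In it Car1 fell, 5 did not pass, and 2 fell when adjusted over the list alone, Car1 and the heme synthesis enzyme Alas2 (-0.98 ± 0.19, adjusted p = 0.0925 over all genes). The hepatocyte markers passed camera upward (12 measured, 0 passing, median 0.06, adjusted p = 0.0208), with adjusted p = 0.240 with an estimated correlation. With the split of arrays 1 and 2 from arrays 3 and 4 as a term, the hepatocyte markers did not pass (adjusted p = 0.0597). The mitochondrial respiratory chain (median 0.07, adjusted p = 1.21e-06) and periportal hepatocyte genes (median 0.12, adjusted p = 0.00385) also passed camera upward, each with adjusted p = 0.240 with an estimated correlation. So did the p53 response (median 0.07, adjusted p = 0.0148, and adjusted p = 0.417 with an estimated correlation), ribosomal proteins (median 0.03, adjusted p = 0.0200, and adjusted p = 0.666 with an estimated correlation) and fibrosis genes (median 0.06, adjusted p = 0.0420, and adjusted p = 0.576 with an estimated correlation). The fibrosis median was 0.09 within arrays 1 and 2 and -0.02 within arrays 3 and 4, and the other 17 lists that passed camera had the same sign in both. The periportal call was lost after quantile normalization (adjusted p = 0.0898) or cyclic loess (0.0676), as were those of the fibrosis, ribosomal, hepatocyte and lipoprotein lists. Of the members of the respiratory chain, periportal, p53, ribosomal and fibrosis lists 0 passed over all genes in limma, and at an unadjusted p of 0.05 11 respiratory chain, 5 periportal, 1 p53, 2 ribosomal and 0 fibrosis genes were higher. Across the 42 lists, 18 passed camera, 15 upward and 3 downward. The female-biased and male-biased lists were the 2 that held with an estimated correlation. By fry, which asks whether a list moves one way without comparing it with other genes, 5 lists held: these same 2, fatty acid uptake and binding, fetal liver genes, and erythroid cell and blood.

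The arrays also fell apart by their number in both groups. The first principal component, with 38.0% of the variance, gave arrays 3 and 4 of each group higher scores than arrays 1 and 2 of that group, and the second, with 23.9%, separated HNF6KO from WT. On the first component HNF6KO arrays also scored higher than the WT arrays on the same side of the split. With the group in the model, 1383 genes differed between arrays 3 and 4 and arrays 1 and 2, 1069 higher and 314 lower on arrays 3 and 4. Kupffer cell and liver endothelial markers were among those higher there, with median log2 differences of 0.82 and 0.66. Between HNF6KO and WT the Kupffer list had a median of 0.07 (camera adjusted p = 0.342) and the endothelial list one of 0.11 (adjusted p = 0.0776). With an estimated correlation the adjusted p was 0.846 for the Kupffer and 0.816 for the endothelial list. The fits that follow used the preset correlation. The endothelial list passed upward with this array split as a term (adjusted p = 0.00654), with array quality weights (median 0.33, adjusted p = 1.34e-04), and also without WT array 3 (adjusted p = 6.65e-04), WT array 4 (0.0205), HNF6KO array 1 (0.0433) or HNF6KO array 2 (median 0.33, adjusted p = 1.08e-05), and within arrays 3 and 4 (median 0.17, adjusted p = 0.00123). The Kupffer list did not pass with the term (adjusted p = 0.236). It passed upward with array quality weights (median 0.39, adjusted p = 0.00638), without HNF6KO array 2 (median 0.31, adjusted p = 0.00889) and within arrays 3 and 4 (median 0.22, adjusted p = 1.61e-04). Without HNF6KO arrays 3 and 4 the Kupffer list passed downward (median -0.39, adjusted p = 0.0404). Weighting the arrays, or leaving out arrays of 1 group, counts the sides of the array split unequally between the groups. Those fits cannot tell a shift of either list between the groups from the split. Neutrophil (-0.13, adjusted p = 0.0172), exocrine pancreas (-0.12, 0.0449) and adipose markers (-0.13, 0.0246) passed downward within arrays 3 and 4. With the term, 245 genes differed between HNF6KO and WT (107 higher and 138 lower), all 78 among them. Genes that gained a call with the term include Clock, Acacb, Fmo1 (adjusted p = 0.0126), Nampt (0.0235), Hal (0.0235), Alas2 (0.0296) and Cyp2c38 (0.0383). Female-biased risers numbered 7 and male-biased fallers 10 with the term. Onecut1 had a log2 change of -0.83 within arrays 1 and 2 (adjusted p = 0.171) and of -1.80 within arrays 3 and 4 (adjusted p = 0.00140). Within arrays 1 and 2 alone 22 genes passed, and within arrays 3 and 4 alone 77.

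**Figure D4:**
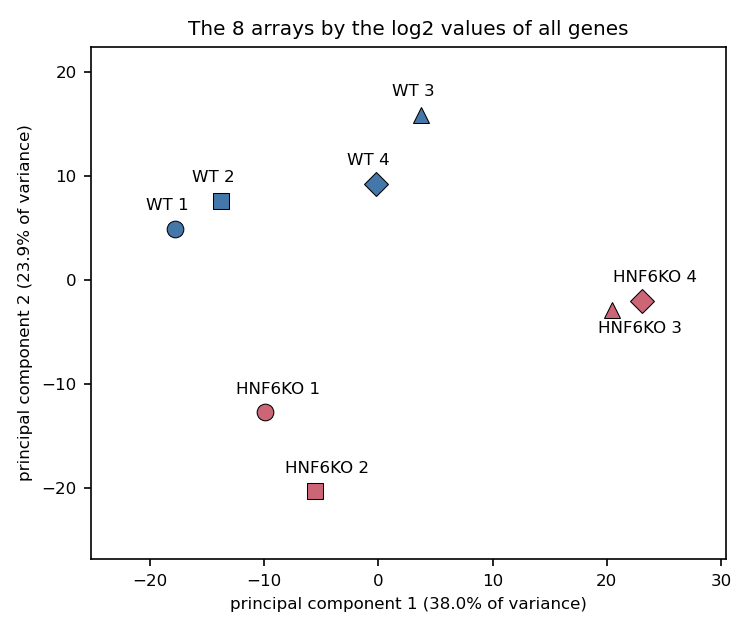
The 8 arrays placed by the log2 values of all genes on the first principal component (38.0% of variance, horizontal axis) and the second (23.9%, vertical axis), WT in blue and HNF6KO in red. Arrays 3 and 4 of each group lie to the right of arrays 1 and 2 of that group, and the HNF6KO arrays lie below the WT arrays.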

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

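Of the tests in this part, the fits and regroupings of the arrays with the array split (numbers 1 and 2 against 3 and 4) as a term and the test of blood content were chosen after the result was seen. Among the named genes, 7 samples lay far from the other 3 of their group, with a gap to the nearest of them above Dixon's 95% limit for 4 values. In WT these were array 2 for Hdac3 (log2 9.19), array 1 for Slc27a5 (11.99) and array 4 for Slco1a4 (8.08). In HNF6KO they were array 2 for C6 (10.30) and Mup3 (12.03), array 1 for Slc27a5 (12.39) and array 4 for Acot1 (6.45). Chance alone marks about 1 in 20 groups, which is 5.7 of the 114 combinations of gene and group looked at. C6 and Mup3, which passed the threshold, had groups that did not overlap even so. Of 1612 probe sets with no single gene symbol, which took no part in the gene comparison, 1 passed the threshold when every probe set was tested on its own. It was lower in HNF6KO by a log2 change of -1.47. That is 0.0620% of such probe sets, against 0.399% of genes in the gene comparison, where the adjustment was over genes and not over all probe sets.

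Of the 35 splits of the 8 arrays into 4 and 4, 2 gave at least the 78 genes of HNF6KO against WT, the real split among them, so this count does not exclude chance, and the other, of arrays 1 and 2 from arrays 3 and 4, gave 807, which points to a structure of the samples. With that structure as a term the real split gave 245 genes and the highest of the others 0, but the 18 splits with 2 arrays of each side in both groups are too few for a share under 0.05 (1 of 18 reached the real count). A difference of signal scale left in the deposited values is argued against by counts of 82 genes after quantile normalization (61 shared) and 58 after median centring (56 shared). The 10 non-hepatocyte marker lists had medians within 0.107 of 0 in the main fit, but a shared shift is not excluded. Cholangiocyte, lymphocyte, neutrophil, blood, pancreas, adipose and muscle markers had median levels of 5.78 to 6.54, below the median gene (6.97), where changes are understated. With array quality weights stellate markers (median 0.12, camera adjusted p = 0.0354) passed upward besides endothelial and Kupffer ones, and pancreas markers downward (-0.08, 0.0460). Shifts of single cell types stay open. The endothelial list passed upward with the array split as a term (camera adjusted p = 0.00654). The blood list passed downward (mean -0.38, 6 of 6 members below 0, adjusted p = 0.00303, but 0.240 with an estimated correlation). Of its 6 members 3 were dimmer than the median gene, and its adult globin genes were not analysed here. Endothelial and Kupffer medians reached 0.33 and 0.39 with array quality weights and 0.33 and 0.31 without HNF6KO array 2. Both lists were higher on arrays 3 and 4, and those 2 fits count the sides of the array split unequally between the groups. They cannot tell a shift between the groups from the split. HNF6 loss, the difference the design names, may underlie the count, as may differences of litter, cage or handling, which the labels do not record.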

How the results depend on the processing

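Fits with the array split (numbers 1 and 2 against 3 and 4) or without HNF6KO arrays 3 and 4 were chosen after the data were seen, and the other alternatives before. The count of 78 genes stayed within 1.5 times without HNF6KO array 1 (79) or 2 (64), within arrays 3 and 4 (77), and under quantile normalization (82, 61 shared), median centring (58, 56 shared), cyclic loess (80), no dim genes (83), mean probe sets (77), every probe set (71) and an intensity trend (56). Array quality weights, from 0.350 for HNF6KO array 1 to 2.00 for HNF6KO array 3, gave 202 genes (101 higher, 101 lower); the cause was not tested. The plain two-sample test, which does not share variance between genes, gave 2 (1 higher, 1 lower), with Onecut1 at -1.32 and adjusted p = 0.194. By construction, an adjusted p of 0.01 gave 14 (7 higher, 7 lower), one of 0.1 gave 162 (73 higher, 89 lower), and a 1.5-fold minimum gave 36 (12 higher, 24 lower). The array number as a replicate block gave 125 (53 higher, 72 lower), 58 of them among the 78. The same-number correlations were 0.44, 0.17, 0.51 and 0.02, so the numbers do not show pairs. Under this block liver transcription factors (adjusted p = 0.00668), partner factors (0.0348) and endothelial markers (0.00668) also passed, as did Clock (0.0489), while hepatocyte markers (0.0818), Gstp1 (0.0627), C2 (0.0660) and Mthfd1 (0.0863) did not. The array split as a term gave 245 (107 higher, 138 lower). Arrays 1 and 2 alone gave 22 (8 higher, 14 lower) with Onecut1 at -0.83, and arrays 3 and 4 alone 77 (50 higher, 27 lower). Without HNF6KO arrays 3 and 4 the count was 19 (8 higher, 11 lower) with Onecut1 at -1.06. The cause of these differences was not tested. Leaving out 1 array gave 16 to 79 genes (7 to 41 higher, 9 to 38 lower), Onecut1 at -1.45 to -1.23, and 14 to 21 lists. Of the 18 lists, 12 held whichever array was left out. The others lost their call without WT array 1 (lipoprotein, cholesterol, p53, fibrosis, hepatocyte), WT array 2 (lipoprotein, cholesterol, fibrosis), WT array 3 or 4 (ribosomal), HNF6KO array 1 (fibrosis), 2 (cholesterol, ribosomal, hepatocyte), 3 (lipoprotein, p53, fibrosis, hepatocyte) or 4 (lipoprotein, cholesterol, p53). Fatty acid oxidation gained one without WT array 4 or HNF6KO array 3 or 4, and exocrine pancreas without HNF6KO array 1 (0.0440). The count was 26, 16, 28 and 40 without WT arrays 1 to 4, and 27 and 30 without HNF6KO arrays 3 and 4, while the fallers alone were 30 without HNF6KO array 2. Over its alternatives Onecut1 kept its direction, with adjusted p from 0.00140 to 0.194. The dim filter took out Slc22a27 and Spink1, so it tested neither. Of the 30 named genes past the threshold, 20 held under the alternatives chosen before that tested them, other than leaving out arrays, the plain test and the changed thresholds. The other 10 were lost after quantile normalization (Gstm2, Mpv17l, Mbl1, Mthfd1), cyclic loess (Gstm2, Mbl1, Mthfd1), median centring (Spink1, Sult1b1, Gstp1, C2, Pcna), the intensity trend (Spink1, Slco1a1, C2, Pcna, Mthfd1), the dim filter (Mthfd1), every probe set (Gstp1) or the block, with adjusted p up to 0.145 for Mthfd1. Quantile normalization and cyclic loess each ended the calls of the lipoprotein, periportal, fibrosis, ribosomal and hepatocyte lists and made one for fatty acid oxidation, for 14 lists in all. Array quality weights ended those of cholesterol and ribosomal genes and made ones for Kupffer, endothelial, stellate and pancreas markers. Of the lists, 18 passed, against 11 without dim genes, 2 with an estimated correlation and 5 by fry. Under the dim filter blood, lymphocyte, neutrophil and pancreas had under 5 genes and went untested. It ended lipoprotein, ribosomal and hepatocyte calls (medians still 0.03, 0.03 and 0.06). It also ended p53, fibrosis and fetal liver calls (now 0.04, 0.04 and 0.07). No cause was tested for these losses or fry. The estimated correlation gave the highest adjusted p of the alternatives chosen before for 15 of the 18. By the direction of the test, 3 list results reversed: cholesterol synthesis in arrays 3 and 4 (median -0.030, where the test points upward, adjusted p = 0.511), and, without HNF6KO arrays 3 and 4, the p53 response (-0.026, adjusted p = 0.644) and Kupffer markers (-0.39, adjusted p = 0.0404). The last 2 came from a fit that removed arrays of 1 side of the array split from 1 group. Both lists were higher on arrays 3 and 4 than on arrays 1 and 2 (medians 0.24 for p53 and 0.82 for Kupffer markers). No cause was tested for any of the 3. The median alone changed sign in 2 other called lists, ribosomal proteins without HNF6KO array 2 (-0.01, adjusted p = 0.507) and fibrosis in arrays 3 and 4 (-0.02, adjusted p = 0.553). Dim genes limit all of these, as their fold changes are understated.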

Other observations

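Apart from the list tests of pericentral, gluconeogenesis, acute phase and unfolded protein genes and of the growth hormone list, which were set beforehand, the tests in this part were chosen after the result was seen. Some liver programs did not pass the list test between the groups. Pericentral hepatocyte genes had a median log2 change of -0.08 (20 measured, camera adjusted p = 0.334), gluconeogenesis and glycogen genes one of -0.04 (18 measured, adjusted p = 0.965), acute phase genes one of 0.04 (25 measured, adjusted p = 0.435), and unfolded protein response genes one of -0.02 (26 measured, adjusted p = 0.633). In these 4 lists 0 members passed in limma over all genes. At an unadjusted p of 0.05 the counts were 2 higher and 1 lower for the pericentral list, 1 and 1 for gluconeogenesis, 0 and 2 for acute phase, and 1 and 0 for the unfolded protein response. The acute phase list passed upward without WT array 4 (median 0.15, adjusted p = 9.48e-04) or HNF6KO array 1 (0.12, adjusted p = 0.0411), and within arrays 1 and 2 (0.17, adjusted p = 0.0212). With the split of arrays 1 and 2 from arrays 3 and 4 as a term, Pfkfb3 (-1.35 ± 0.33, adjusted p = 0.0164), Ppp1r3g (-0.43 ± 0.29, adjusted p = 0.0271) and Crp (-0.68 ± 0.13, adjusted p = 0.0474) passed, where the changes and SE are those without the term. These 3 genes were chosen after their values were seen.

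The array numbers also separated some clock genes. Of the core circadian clock list, written beforehand, 6 of 19 members differed between arrays 3 and 4 and arrays 1 and 2, and the list passed camera upward (median 0.12, adjusted p = 0.0395, but 0.532 with an estimated correlation). Of the clock output list 6 of 22 differed, and it passed as well (median 0.28, adjusted p = 7.86e-04, but 0.325 with an estimated correlation). Among 11 clock genes picked afterwards, Cry1 (log2 0.39 ± 0.09, adjusted p = 0.0359), Clock (0.24 ± 0.06, adjusted p = 0.0367) and Per3 (-0.52 ± 0.12, adjusted p = 0.0367) differed between arrays 3 and 4 and arrays 1 and 2 with the group in the model. Cry1 and Per3 were chosen after their values were seen. Nr1d1 had a log2 difference of -0.63 ± 0.23 (adjusted p = 0.130). None of the 11 differed by more than 1 on the log2 scale, and their differences ran from -0.63 to 0.74. Whether this reflects time of dissection was not tested, since the labels give 1 time for every sample.

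In HNF6KO males the list of female-biased liver genes shifted upward, with 3 of 28 members risen and 8 below 0, and the male-biased list downward, with 6 of 31 fallen. Female animals among the HNF6KO samples are argued against by Xist, which differed by a log2 of 0.0124 and lay low in both groups (4.82 ± 0.03 in WT, 4.84 ± 0.13 in HNF6KO), and by 3 Y-linked genes, which were not lower (8.32 ± 0.11 in WT, 8.54 ± 0.11 in HNF6KO). Probe sets shared between near-identical relatives are argued against as the whole cause for the male-biased list, since its 15 members outside such families had a median of -0.18 (camera p = 1.71e-04, and p = 0.0197 with an estimated correlation, exact p = 0.0286). For the 11 female-biased members outside families this cannot be told apart, as their median was 0.07 and the tests did not all pass (camera p = 0.0172, and p = 0.0509 with an estimated correlation, exact p = 0.0571). A changed response to growth hormone, whose pulses set the sex bias of these genes, may contribute, and it stays open because the growth hormone and STAT5 list had adjusted p = 0.213 and transcripts of a pathway need not move with its activity.

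Arrays 3 and 4 differed from arrays 1 and 2 in 1383 genes with the group in the model. A difference of signal scale left in the deposited values is argued against, since 1304 genes differed after quantile normalization. Endothelial markers were higher in arrays 3 and 4 for 18 of 18 members (median 0.66, camera adjusted p = 1.07e-12, but adjusted p = 0.532 with an estimated correlation) and Kupffer markers for 16 of 19 (median 0.82, adjusted p = 7.33e-07, also adjusted p = 0.532 with an estimated correlation). More non-hepatocyte cells in those samples may explain this in part, but of 4 resident non-hepatocyte lists only 2 rose by over 0.2, with stellate markers at 0.17 (12 of 16 above 0, adjusted p = 6.07e-04, but 0.366 with an estimated correlation) and cholangiocyte markers at -0.02. Cholangiocyte markers lay at a median level of 6.10, near the dim end of the arrays, so the explanation cannot be told apart from others, and no biological one was tested.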
